A study of Mus musculus with 5 samples.

How the data were processed

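Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MS5 cells, an established mouse bone marrow stromal line, at passage 11. Per the labels' protocols, the cells received TGF-β1 at 10 ng/mL for 5 h, with or without pioglitazone at 20 ng/mL, and were fixed with formaldehyde. Chromatin was precipitated with an antibody against p300 or against c-Jun. The series has 5 samples: 4 ChIP libraries, 1 for each antibody and treatment, and 1 pooled input. The 4 ChIP libraries each have a deposited peak list, and no file of the input was used here. The labels give no replicate libraries, and no batch or date.

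Per the submitters' processing notes, Bowtie2 (version 2.3.4.3), SAMtools (version 1.9) and HOMER (version not given in the sources used here) were used with the mouse build mm9. The role and order of these tools, the settings of the peak caller, the treatment of duplicate reads, the use of the input and the exclusion of any regions are not given in the sources used here. Peaks were deposited as a separate list for each ChIP library; whether the pooled input served as a common background is not stated. Each list gives a chromosome, a start, an end, a name made of the chromosome and a number, a score and a strand. The deposited score is 1 for every peak of all 4 lists and therefore carries no height, enrichment or p-value. All peaks of a list have the same width: 247 bp for p300 without pioglitazone, 227 bp for p300 with it, 249 bp for c-Jun without it and 235 bp for c-Jun with it. No read count is in the lists, so the sequencing depth of each library is unknown, and a difference in depth or in enrichment between libraries would move the number of peaks called.

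The positions were taken as mm9. On chromosome 7, between 42 and 103 peaks per list lay beyond the last gene of the GRCm38 gene table that was at hand, by up to 7.19 Mb, which excludes GRCm38 as the build of the lists. No mm9 sequence or annotation was used here and coordinates were not converted, so peaks were not assigned to genes. The planned comparisons of gene lists, of the share of peaks at promoters and of AP-1 motifs were therefore not run, and sites are named by position only, counted from 1 at the chromosome start, as the rule fixed before the data were examined provides for that case.

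Peaks of different lists counted as shared when they overlapped by at least 1 bp. A p300 or c-Jun peak listed without pioglitazone is called retained when a peak of the same antibody listed with pioglitazone overlaps it, and lost otherwise. A peak listed with pioglitazone that overlaps none of the same antibody without it is called gained. These words describe the lists and not a test of binding. Overlaps were computed in Python (version 3.11.15, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1) from the distance between peak centres. They were checked against bedtools (version 2.31.1), which gave the same number in 24 of 24 pairwise comparisons at 1 bp and at 50% of both peaks. The overlap that chance would give was taken from 100 shifts of a whole list by 50 to 500 kb in either direction. Shares carry exact (Clopper-Pearson) 95% intervals. Differences of shares carry intervals combined from these, or Mantel-Haenszel weighted intervals where peaks were compared within parts of a list, and odds ratios carry Robins-Breslow-Greenland intervals. All of these cover counting error only. With 1 library per group there is no replicate check of any difference between treatments, and no p-value is given.

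The order of the rows in each list stood in for peak strength, because the score holds none. On every chromosome with more than 10 peaks, row order followed the number in the peak name, with a rank correlation of at least 0.823 in all 4 lists. Among p300 peaks shared by both treatments, row order in one list went with row order in the other (Spearman's rho 0.81 across 16077 peaks), and among shared c-Jun peaks rho was 0.74 across 7783 peaks. Peaks are not independent replicates. Lists were divided into 10 or 100 equal parts of this order. No source states what the rows were sorted by.

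Domains were formed from the peaks of all 4 lists by joining neighbouring centres no more than 12.5 kb apart, and, where 1 list is examined alone, from that list in the same way. The sites named are, for each antibody, the 5 first in the list among the retained, the lost and the gained peaks. The 5 domains with most peaks, and for each antibody the 5 with the largest fall and the 5 with the largest rise in listed peaks, are also named, by a rule set after the files had been seen but before the domains were counted. The functions were tested on simulated data made from the real p300 and c-Jun lists without pioglitazone. Where retention depended on list order alone, the difference within 10% steps of the list came out at -0.06 percentage points (95% interval -1.14 to 1.02) for the simulated p300 list of 31466 peaks and at -1.36 (-2.84 to 0.11) for the simulated c-Jun list of 17044 peaks. Where a difference of 10 points was built in, 10.4 and 10.6 points were found. In these simulations, apart from the built-in difference, neither retention nor the presence of a second factor changed with row order inside a 10% step. They check the functions only. They cannot show whether row order inside a step, or row order as an imprecise measure of strength, leaves a difference in the real lists.

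The alternatives fixed before the data were examined and run here were an overlap of 50% of both peaks, centres within 100 bp, peaks within 500 bp of each other, and autosomes and X only. Those that needed a peak score could not be run as planned, and were replaced, after the lists had been seen, by cuts on row order.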

Results

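Binding of p300 and c-Jun was profiled by ChIP-seq in MS5 mouse bone marrow stromal cells exposed to TGF-β1, a cytokine that drives fibroblasts to deposit matrix. p300 is a histone acetyltransferase and transcriptional coactivator found at active enhancers and promoters. c-Jun is a subunit of the AP-1 transcription factor. In each pair of libraries, 1 also received pioglitazone, a thiazolidinedione that activates the nuclear receptor PPARγ, and the series title places the work in the resolution of myelofibrosis, the replacement of bone marrow by fibrous tissue. Each of the 4 combinations of antibody and treatment was a single library, so every difference below is between 2 libraries and has no replicate check. The lists held 31466 p300 peaks without pioglitazone, 21994 p300 peaks with it, 17044 c-Jun peaks without it and 13325 c-Jun peaks with it. They covered 7.77, 4.99, 4.24 and 3.13 Mb. Sequencing depth is unknown, and intervals cover counting error only. Chromosome 2 carried the most peaks in every list, from 1073 for c-Jun with pioglitazone to 2434 for p300 without it.

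The first comparison asked where p300 was listed with and without pioglitazone in TGF-β1-treated cells. The list with pioglitazone was 69.9% as long as the list without it. Of the 31466 p300 peaks without pioglitazone, 16077 were retained, which is 51.1% (95% interval 50.5 to 51.6), and 15389 were lost. With pioglitazone, 5917 of 21994 p300 peaks were gained, 26.9% (26.3 to 27.5). The retained share was 76.1 times the mean of shifted lists, 0.671%, whose highest value was 0.877%. The shorter list alone caps the retained share at 69.9%.

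**Figure D1:**
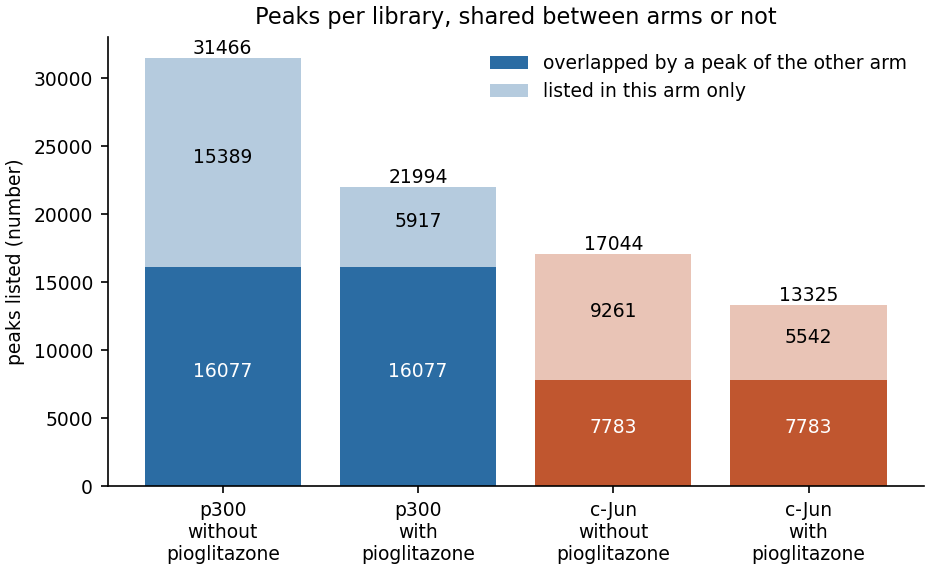
Number of peaks listed in each of the 4 libraries (vertical axis), split into peaks overlapped by at least 1 bp by a peak of the same antibody in the other treatment (dark) and peaks listed in that library only (light). p300 had 16077 shared peaks of 31466 without and 21994 with pioglitazone, and c-Jun had 7783 of 17044 and 13325.

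Loss of p300 peaks followed the order of the list. In the first 10% of the p300 list without pioglitazone, 120 of 3147 peaks were lost, 3.81% (3.17 to 4.54), and the lost share was higher in each following 10% step, up to 86.7% (85.4 to 87.9) in the last. Of those 120 peaks, 44 had a p300 peak with pioglitazone within 500 bp. Gained p300 peaks made up 2.23% (1.65 to 2.93) of the first 10% of the list with pioglitazone and 56.9% (54.8 to 59.0) of the last. Of the 49 gained peaks in that first 10%, 37 had a p300 peak without pioglitazone within 500 bp.

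The p300 peak at chromosome 6, 113256951 to 113257197, was at position 1 of both p300 lists, and the one at chromosome 7, 134920606 to 134920852, at position 2 of both. Retained peaks at positions 3, 4 and 5 without pioglitazone lay on chromosome 15 (101198977 to 101199223), chromosome 16 (25220706 to 25220952) and chromosome 6 (100009927 to 100010173). They stood at positions 20, 14 and 11 with pioglitazone. The first lost p300 peak was at position 238 of 31466, on chromosome 2 (148345654 to 148345900), with the nearest p300 peak of the other list 2184 bp away, centre to centre. The next lost peaks were on chromosome 8 (87505018 to 87505264), chromosome 6 (31038826 to 31039072), chromosome 9 (23269465 to 23269711) and chromosome 1 (194566309 to 194566555), at positions 351, 355, 544 and 546. The centre of the lost peak on chromosome 6 lay 274 bp from that of the gained peak at 31038562 to 31038788, which was at position 180 with pioglitazone. The other gained p300 peaks nearest the top were on chromosome 11 (109678296 to 109678522 and 78894531 to 78894757), chromosome 6 (113640102 to 113640328) and chromosome 8 (109730681 to 109730907). All 5 of these gained peaks had a p300 peak without pioglitazone with its centre 274 to 811 bp away.

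The second comparison asked the same of c-Jun. The c-Jun list with pioglitazone was 78.2% as long as the list without it. Of 17044 c-Jun peaks without pioglitazone, 7783 were retained, 45.7% (44.9 to 46.4), against 0.409% in shifted lists, and 9261 were lost. With pioglitazone, 5542 of 13325 c-Jun peaks were gained, 41.6% (40.8 to 42.4). In the first 10% of the c-Jun list without pioglitazone 158 of 1705 peaks were lost, 9.27% (7.93 to 10.7), and in the last 10% 82.5% (80.6 to 84.3). With list lengths made equal between treatments by row order, the retained share was 52.9% (52.0 to 53.8) for c-Jun and 64.6% (64.0 to 65.3) for p300. Lengths were not matched between the antibodies, with 13325 c-Jun and 21994 p300 peaks per list.

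The first 2 c-Jun peaks, on chromosome 8 (74134832 to 74135080) and chromosome 17 (34052890 to 34053138), held positions 1 and 2 with and without pioglitazone. Those on chromosome 2 (170336638 to 170336886), chromosome 9 (106183465 to 106183713) and chromosome 7 (16705246 to 16705494) were at positions 3, 4 and 5 without and 4, 3 and 7 with it. Of these 5 retained c-Jun peaks, 1 overlapped a p300 peak without pioglitazone and 0 did with it. The first lost c-Jun peak was on chromosome 16 (57391519 to 57391767), at position 114 of 17044, and the nearest c-Jun peak with pioglitazone lay 29396 bp away, centre to centre. Further lost c-Jun peaks were on chromosome 8 (19995655 to 19995903 and 19871574 to 19871822), chromosome 15 (101198981 to 101199229) and chromosome 10 (79626616 to 79626864). The site on chromosome 15 is the one at position 3 of the p300 list: p300 was listed there in both treatments, and c-Jun without pioglitazone only, with the centre of the nearest c-Jun peak with pioglitazone 1849 bp away. Gained c-Jun peaks nearest the top were on chromosome 8 (19994336 to 19994570), chromosome 17 (28465400 to 28465634), chromosome 19 (42092425 to 42092659), chromosome 1 (90967033 to 90967267) and chromosome 10 (69958051 to 69958285), at positions 268 to 464 of 13325. The centre of the gained peak on chromosome 8 lay 1326 bp from that of the lost one at 19995655.

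**Figure D2:**
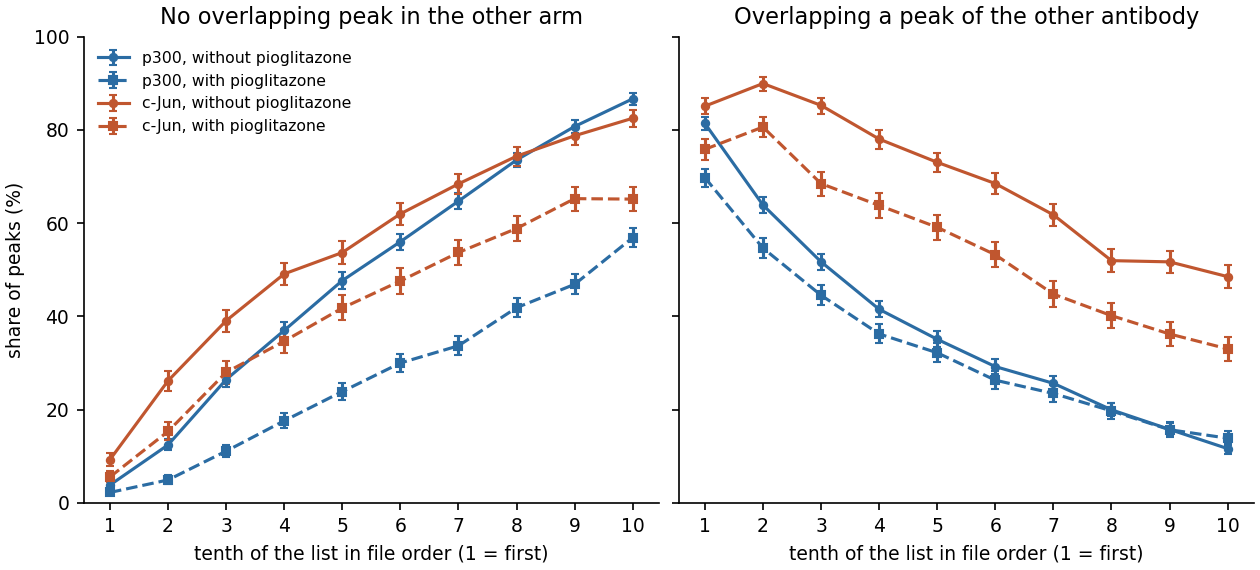
Share of peaks (vertical axis, %) by 10% step of each list in row order (horizontal axis, 1 to 10 from the start of the list) that have no overlapping peak in the other treatment (left) or that overlap a peak of the other antibody in the same treatment (right). Bars are exact 95% intervals. The unshared share of p300 without pioglitazone goes from 3.81% to 86.7%, and the c-Jun overlap with p300 is lower with pioglitazone than without it in each step.

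The third comparison asked how far c-Jun and p300 occupied the same sites. Without pioglitazone 11828 of 17044 c-Jun peaks overlapped a p300 peak, 69.4% (68.7 to 70.1), and with pioglitazone 7400 of 13325 did, 55.5% (54.7 to 56.4). Shifted lists gave 0.981% and 0.654%. The p300 list with pioglitazone is shorter. When the p300 list without pioglitazone was shortened from its end to the same length, 60.6% (59.9 to 61.3) of c-Jun peaks without pioglitazone overlapped it. In the first 10% of each c-Jun list the shares were 85.1% (83.3 to 86.8) without and 75.8% (73.5 to 78.1) with pioglitazone. With the shortened p300 list, the share without pioglitazone in that first 10% was 83.0% (81.1 to 84.7). Seen from p300, 37.6% (37.1 to 38.1) of p300 peaks overlapped c-Jun without pioglitazone and 33.7% (33.0 to 34.3) with it. Where the factors overlapped, the median distance between their peak centres was 40 bp without and 47 bp with pioglitazone, against 38 bp between retained p300 peaks of the 2 treatments.

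Over the whole lists, sites with both factors were retained more often than sites with 1. Of p300 peaks that overlapped c-Jun without pioglitazone, 74.1% (73.3 to 74.9) were retained, and of the 19638 p300 peaks alone 37.2% (36.6 to 37.9) were. The difference was 36.8 percentage points (35.8 to 37.9) and was 15.8 (14.6 to 16.9) within 10% steps of the p300 list. Within such steps it was 15.4 (14.0 to 16.9) among the first 50% of p300 rows, matched to the full other lists. It was 14.2 (12.9 to 15.5) at list lengths made equal between treatments, and 7.61 (6.10 to 9.11) with all lists cut to their upper 50%. That last cut also changed which peaks counted as alone. Of the 15733 upper p300 rows, 6102 overlapped the cut c-Jun list and 8611 the full one. Of c-Jun peaks with p300, 56.3% (55.4 to 57.2) were retained, and of the 5216 c-Jun peaks alone 21.5% (20.4 to 22.7). That difference was 34.8 points (33.4 to 36.2) and 22.7 (21.2 to 24.1) within 10% steps of the c-Jun list, or 13.0 (11.0 to 15.1) with all lists so cut. Near the start of the c-Jun list the gap was small or absent. Between 2% and 5% of that list, 94.1% (83.8 to 98.8) of peaks alone and 94.1% (91.6 to 96.1) of peaks with p300 were retained. Between 5% and 10% the shares were 71.8% (59.9 to 81.9) and 86.8% (84.2 to 89.1). Gained p300 peaks overlapped c-Jun with pioglitazone in 10.9% (10.1 to 11.7), and p300 peaks listed in both treatments in 42.0% (41.3 to 42.8). These shares are not adjusted for list order, and gained peaks stood low in the list. Among the first 50% of rows with pioglitazone the shares were 19.2% and 51.3%. Within 10% steps of the p300 list with pioglitazone, a comparison added after the lists were seen, the overlap share of gained peaks minus that of peaks in both lists was -20.0 points (-21.2 to -18.7). It was -23.9 (-26.3 to -21.4) among the first 50% of rows, -20.8 (-22.2 to -19.5) at equal lengths and -12.4 (-14.4 to -10.5) with all lists cut to their upper 50%. The retained shares of peaks alone also depended on the rows used: 44.8% for p300 and 35.0% for c-Jun with all lists cut to their upper 50%, and 61.3% and 42.4% among the first 50% of rows without pioglitazone, matched to the full other list.

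At the 11828 sites with both factors without pioglitazone, both were retained at 5545, 46.9% (46.0 to 47.8). p300 was retained and c-Jun lost at 3218 sites, 27.2% (26.4 to 28.0), p300 lost and c-Jun retained at 1116, 9.44% (8.91 to 9.98), and both were lost at 1949, 16.5% (15.8 to 17.2). The share with both lost ranged over the alternatives from 7.76%, among the first 50% of p300 rows, to 19.9%, with centres within 100 bp, and the share with both retained from 40.4%, again with centres within 100 bp, to 57.0% among the first 50% of p300 rows. c-Jun was retained at 63.3% (62.3 to 64.3) of the sites that kept p300 and at 36.4% (34.7 to 38.1) of those that lost it. The odds ratio was 3.01 (2.76 to 3.28), and 1.71 (1.55 to 1.9) within 10% steps of both lists. Merging all 4 lists gave 44718 sites. Of these, 5762 (12.9%) were in all 4 lists, 11485 (25.7%) in the p300 list without pioglitazone only and 6001 (13.4%) in both p300 lists and neither c-Jun list.

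**Figure D3:**
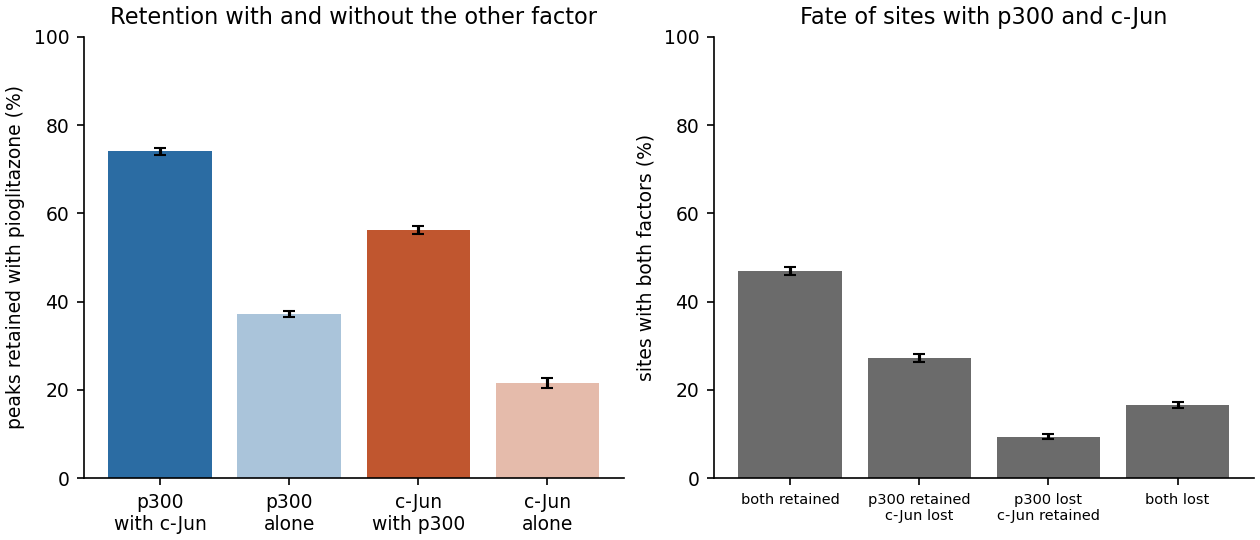
Left, share of p300 and c-Jun peaks without pioglitazone that were retained with it (vertical axis, %), for peaks with and without the other factor, with exact 95% intervals. Right, the 11828 sites with both factors by what the lists with pioglitazone hold (vertical axis, % of sites, exact 95% intervals): p300 peaks with c-Jun were retained in 74.1% and p300 peaks alone in 37.2%, and both factors were retained at 46.9% of shared sites.

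By chromosome, the X had the lowest retained share for both antibodies when the Y, whose lists held at most 2 peaks, was left aside. On X, 43.6% (40.1 to 47.3) of 754 p300 peaks were retained, against 51.3% (50.7 to 51.8) elsewhere, and 36.6% (31.7 to 41.6) of 383 c-Jun peaks, against 45.9% (45.1 to 46.6). X peaks stood low in the lists. Within 10% steps of the list the p300 difference turned to 7.08 points higher on X (4.16 to 10.0), and the c-Jun difference was 3.12 points (-1.21 to 7.45). The sign for p300 depended on the rows used. Among the first 50% of rows without pioglitazone, matched to the full other list, 86.0% of 207 X peaks were retained and the difference was 11.6 points (6.08 to 16.1), but with all lists cut to their upper 50% the X share was 48.3% and the difference -8.31 (-15.3 to -1.23), and -0.996 (-6.33 to 4.34) within the steps. The c-Jun share on X was 67.7% and 44.8% under these cuts. Among autosomes the p300 retained share went from 45.8% (42.9 to 48.8) on chromosome 12 to 54.1% (51.1 to 57.0) on chromosome 18. The c-Jun share went from 39.8% (36.3 to 43.3) on chromosome 4 to 49.9% (45.6 to 54.2) on chromosome 19. Within 10% steps of the list these 2 chromosomes changed order for c-Jun. Chromosome 4 differed from the other chromosomes by 5.51 points (2.27 to 8.75) and chromosome 19 by -4.40 (-8.13 to -0.664). For p300, chromosomes 12 and 18 differed by 1.26 (-1.16 to 3.68) and 2.15 (-0.372 to 4.67). Other autosomes differed more for p300 within these steps. Chromosome 10 differed by -5.92 (-7.79 to -4.06), chromosome 19 by -5.40 (-8.07 to -2.73) and chromosome 4 by 4.26 (2.05 to 6.46).

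Peaks also lay in dense domains. The 4 lists joined into 25240 domains, of which 2219 held at least 5 p300 peaks over the 2 treatments. Fewer p300 peaks were listed with pioglitazone in 1354 of these, more in 353 and as many in 512. For c-Jun, 675 domains held at least 5 peaks, with fewer in 367, more in 167 and as many in 141. The shorter lists with pioglitazone would by themselves give more falls than rises, and these counts were not made at equal list lengths. The domain on chromosome 11 from 117774024 to 117877386 held 13 p300 peaks without and 12 with pioglitazone, and 8 and 7 c-Jun peaks. That on chromosome 8 from 124657082 to 124718175 held 12 and 11 p300 peaks and 10 and 7 c-Jun peaks. On chromosome 1, the domain from 156922064 to 157006594 held 10 p300 and 7 c-Jun peaks in both treatments. The largest fall in listed p300 peaks was 6, in 6 domains, of which 5 are given here. On chromosome 6 (135242443 to 135338083) p300 peaks numbered 15 without and 9 with pioglitazone, on chromosome 17 (29565182 to 29635157) 11 and 5, on chromosome 9 (87978129 to 88013912) and chromosome 4 (144570899 to 144607926) 8 and 2, and on chromosome 3 (136496886 to 136535992) 7 and 1. The largest rise was 3 p300 peaks, in 13 domains, for example from 4 to 7 on chromosome 11 (117166983 to 117214801) and from 2 to 5 on chromosome 11 (76123495 to 76138415).

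The largest falls in listed c-Jun peaks were from 8 to 3 on chromosome 5 (31904797 to 31969040) and from 7 to 2 on chromosome 11 (81810643 to 81859268), where p300 peaks numbered 10 and 7, and 8 and 6. Falls of 4 were seen in 13 domains, among them 2 on chromosome 10 (120013917 to 120103012, from 8 to 4, and 21493427 to 21528278, from 7 to 3) and 1 on chromosome 2 (131532370 to 131587567, from 7 to 3). In the last 2 of these domains the number of p300 peaks was the same in both treatments, 6 and 7. The largest rise was 4 c-Jun peaks, from 2 to 6 on chromosome 13 (53063182 to 53104522), where p300 had 5 in both, and from 0 to 4 in 4 domains. No domain change was tested against replicates.

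**Figure D4:**
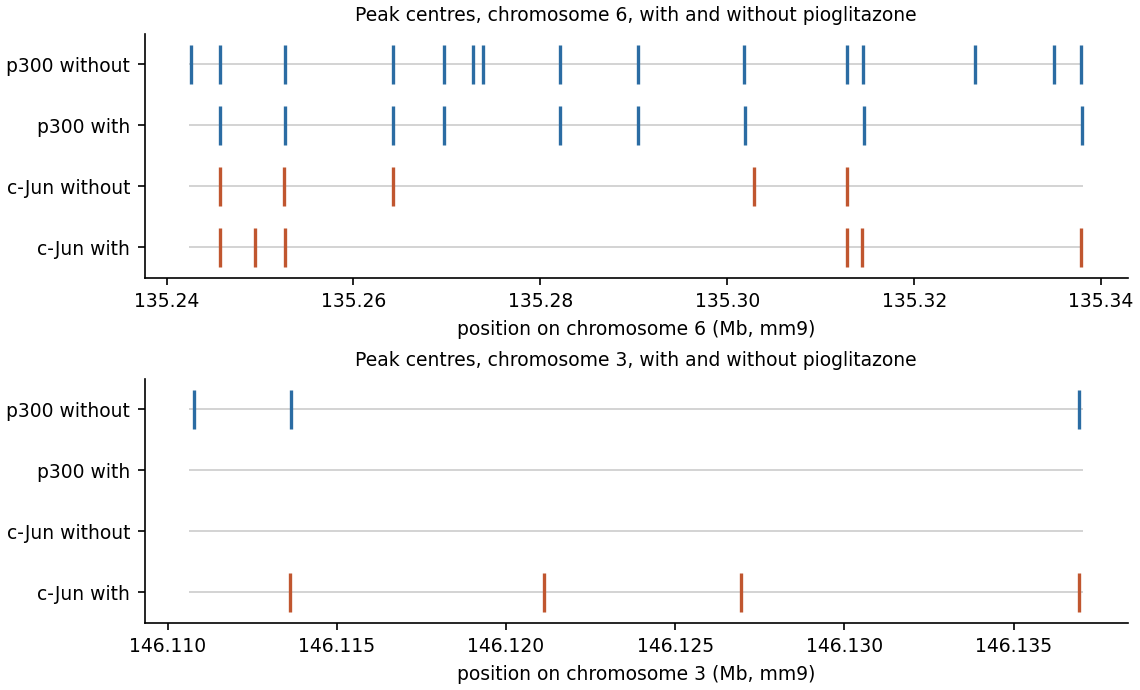
Peak centres (vertical marks) in 4 lists along 2 named domains, with position in Mb on mm9 on the horizontal axis and 1 row per library. On chromosome 6, p300 peaks number 15 without and 9 with pioglitazone; on chromosome 3, 3 p300 peaks without pioglitazone and 0 with it stand above 0 c-Jun peaks without and 4 with it.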

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

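Each peak's name carries a number within its chromosome, which was set against row order above but is used in no comparison of the lists. The numbers have gaps, a feature in data outside the comparisons. Up to the highest number on each chromosome, 47.4% of numbers were missing from the p300 list without pioglitazone and 44.5% from the one with it. For c-Jun 86.0% were missing without and 89.1% with pioglitazone. The highest numbers summed to 59775 and 39644 for p300 and to 122043 and 121910 for c-Jun, where 17044 and 13325 peaks were listed for c-Jun. How the numbers were assigned, and why some are missing, is not given in the sources used here.

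Among the named domains, 9 were flagged because the number of listed peaks moved in opposite directions for the 2 antibodies. Most named domains had been picked for a large change of 1 antibody. Opposite movement was also not rare. Of all 4702 domains in which both antibodies changed, p300 fell and c-Jun rose in 1127, and the reverse held in 614. The differences in the 9 domains were not tested, since each group is 1 library. c-Jun peaks rose by 4, from 0, on chromosome 3 (146110644 to 146137055) and chromosome 9 (113839518 to 113861476), where p300 peaks went from 3 to 0 in both. c-Jun also rose by 4 from 0 on chromosome 11 (69475848 to 69529672), with p300 going from 6 to 4, and on chromosome 2 (167474757 to 167523594), with p300 going from 3 to 2. On chromosome 6 (135242443 to 135338083) c-Jun rose by 1 while p300 went from 15 to 9. p300 rose by 3 while c-Jun fell by 1 on chromosome 11 (117166983 to 117214801), chromosome 6 (117829545 to 117867968) and chromosome 7 (112607098 to 112630940), and while c-Jun fell by 2 on chromosome 16 (14350763 to 14373255).

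Whether the changed peaks of a domain go in the same direction was tested with a prediction made before the counts were seen. If peaks come and go one by one, the number of domains with a net change of at least 4 peaks should lie within the range of 1000 random exchanges of lost and gained labels. The exchanges keep the changed peaks in place, so they cannot show whether changed peaks cluster in domains. For c-Jun there were 20 such domains, within the range of 16 to 44. Of these, 15 were net losses and 5 net gains. The exchanges gave a mean of 2.89 and at most 9 net gains, and a mean of 24.4 net losses. Given where peaks changed, the 4 domains that go from 0 to 4 c-Jun peaks may be no more than independent directions of change produce. For p300 there were 64, under the lowest exchange (86), an outcome that the prediction does not cover. All 64 were net losses, against a mean of 106 net losses in the exchanges. Lost and gained p300 peaks were thus mixed within domains more than the exchanges gave, and the cause was not tested. Over all 4702 domains in which both antibodies changed, p300 and c-Jun fell together in 2576 and rose together in 385, p300 fell and c-Jun rose in 1127, and p300 rose and c-Jun fell in 614 (odds ratio 1.43, 1.24 to 1.66). No biological explanation was tested for the opposite changes.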

How the results depend on the processing

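The cuts on row order and the other joining distances were chosen after the lists had been seen. Requiring 50% of both peaks, or centres within 100 bp, or allowing peaks within 500 bp, gave p300 retained shares of 45.6%, 44.1% and 54.9%, p300 gained shares of 34.7%, 37.0% and 21.5%, c-Jun retained shares of 40.2%, 38.0% and 49.1% and c-Jun gained shares of 48.6%, 51.4% and 37.3%. Under the same settings c-Jun peaks with p300 made up 62.6%, 59.2% and 74.4% without and 47.5%, 45.3% and 61.7% with pioglitazone, so the share was lower with pioglitazone in each. The retention difference between c-Jun peaks with and without p300 was 33.0 points at 100 bp and 36.5 at 500 bp. In the upper 50% of all lists, p300 retained was 56.5% and gained 19.2%, c-Jun retained 51.2% and gained 34.5%, the retention differences 30.1 (p300) and 22.6 points (c-Jun), and c-Jun with p300 71.6% without pioglitazone. Counting only the upper 50% of the counted list gave 74.5% and 11.9% for p300, 64.5% and 25.1% for c-Jun, differences of 24.1 and 26.9 points, and c-Jun with p300 in 82.3% and 69.6%. At list lengths made equal between treatments the values were 64.6% and 35.4% for p300, 52.9% and 47.1% for c-Jun, and 29.0 and 32.7 points. For c-Jun with p300, each p300 list was instead cut to the length of the c-Jun list of its treatment, which gave 53.0% and 43.8%. Those p300 lists still differed in length between treatments, with 17044 and 13325 peaks. With only the p300 list without pioglitazone shortened to the length of the one with it, the share without pioglitazone was 60.6%. Removing the Y moved none of these beyond its interval. For the overlap rules, the direction of the shifts in retained, gained and overlapping shares follows from their construction, since a stricter match can only lower an overlap and a wider one only raise it; the cause of the other shifts was not tested. In the upper 50% of all lists the retention differences within 10% steps were 7.61 (p300) and 13.0 points (c-Jun). They were 15.4 and 22.5 points in the upper 50% of the counted list, and 14.2 and 21.9 at equal lengths. The p300 difference on X changed sign to 11.6 points in the upper 50% of the counted list and 5.92 at equal lengths, and within 10% steps of the list to -0.996 in the upper 50% of all lists; for c-Jun these were 3.21 points for the counted 50% and -2.32 within 10% steps of the upper 50%. The c-Jun difference between domains of at least 5 peaks and single peaks within 10% steps was 3.69 points (-2.10 to 9.47) and changed sign in the upper 50% (-10.8), at equal lengths (-3.63) and with peaks joined at 5 kb (-33.3) or 25 kb (-1.48). The value at 5 kb carries no weight, since such domains then hold 5 c-Jun peaks, of which 1 was retained; the cause of the others was not tested. For p300 that difference was -24.4 points at 5 kb (-43.8 to -5.04), from 16 domain peaks, and -5.68 at 25 kb. Of 311 other values, 107 stayed within the interval of the reported one, 195 moved beyond it and 9, all printed above, changed sign. The planned cuts on a peak score were not run, since the score holds 1 throughout, and neither were the gene list, promoter and motif comparisons with their alternatives, nor leaving out a replicate, since each group has 1 library. No paired analysis was possible because each group has 1 library. Depth, which is unknown, limits every comparison of list lengths.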

Other observations

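At the very top of the c-Jun lists many sites had no p300 peak. In the first 1% of the c-Jun list without pioglitazone, 49.4% (95% interval 41.7 to 57.2) of 170 peaks overlapped p300, against 90.0% (87.1 to 92.5) of the 512 peaks between 2% and 5% of the list. With pioglitazone the shares were 53.4% (44.5 to 62.1) of 133 peaks and 82.5% (78.4 to 86.1) of 400. Between 1% and 2% of the lists the shares were 72.9% (65.6 to 79.5) without and 48.9% (40.1 to 57.7) with pioglitazone. The 86 c-Jun peaks without p300 in the first 1% were retained with pioglitazone in 98.8% (93.7 to 100), and the c-Jun peaks with p300 in the same first 1% in 100% (95.7 to 100). A p300 peak was listed with pioglitazone at 25 of these 86 sites. The c-Jun peaks at positions 1 and 2, on chromosome 8 (74134832 to 74135080) and chromosome 17 (34052890 to 34053138), had no p300 peak in either treatment.

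Dense p300 domains were retained whole less often than list order alone gave. In the p300 list without pioglitazone, 388 domains held at least 5 peaks, and every peak was retained in 17 of them, against a mean of 44.0 and a lowest of 26 in 1000 permutations of retention within 10% steps of the list. Every peak was lost in 5, against a mean of 4.90. For c-Jun, every peak was retained in 3 of 42 such domains, against a mean of 2.07 and a range of 0 to 8. Within 10% steps of the list, p300 peaks in such domains differed from single peaks in retained share by -8.19 points (-10.1 to -6.29), although without regard to list order 58.6% (56.5 to 60.6) were retained against 46.8% (46.0 to 47.6).

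The tests of the 2 patterns that follow use row order as a stand-in for peak strength. The tests of c-Jun overlap in the first 10% and of retention within parts of the lists were chosen after the results had been seen. The shortened p300 list was added after the lists had been seen, but before its value was. A first pattern is the loss of p300 and c-Jun peaks with pioglitazone. A candidate explanation is a lower depth or enrichment of the libraries with pioglitazone, which would remove peaks near the caller's threshold; it was predicted to leave under 5% of the first 10% lost, with over 20% lost counting against it. For p300 the first 10% lost 3.81% and the share was higher in every following 10% step, but the bound of 5% was met under some rules and not others: the loss was 6.04% (5.23 to 6.93) at 50% of both peaks and 6.93% (6.06 to 7.87) with centres within 100 bp, against 2.41% within 500 bp, 2.29% in the upper 50% of all lists and 2.5% at equal lengths. For c-Jun the first 10% lost 9.27%, with a range from 4.10% in the upper 50% of all lists to 15.3% with centres within 100 bp, so neither antibody decides for or against it. An effect of pioglitazone on p300 binding cannot be told apart from a difference between libraries here, since each treatment has 1 p300 library.

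A second pattern is the overlap of p300 and c-Jun: c-Jun overlapped p300 less often with pioglitazone, and over the whole lists shared sites were retained more often and together. The shorter p300 list is not the whole cause of the lower overlap. With the p300 list without pioglitazone shortened to the same length, 60.6% (59.9 to 61.3) of c-Jun peaks still overlapped p300, against 55.5% (54.7 to 56.4) with pioglitazone. In the first 10% of the c-Jun lists the share was also lower, by -9.26 points with minus without, but the p300 lists there differed in length. With the shortened p300 list, the shares in the first 10% were 83.0% (81.1 to 84.7) without and 75.8% (73.5 to 78.1) with pioglitazone. Peaks low in the c-Jun lists are therefore not the whole cause either. The first 10% fixes a position in the list and not a strength. It cannot show whether peaks were weaker throughout a less enriched library. The first rows of the c-Jun lists, many of them without p300, also weigh on the size of the gap in the first 10%. List order is not the whole cause of the higher retention of shared sites. The differences within hundredths of the lists were 15.5 points (14.4 to 16.7) for p300 and 23.0 (21.6 to 24.4) for c-Jun. They were 15.1 and 23.6 in the upper 50% of the counted list, and 14.0 and 22.4 at equal lengths. With all lists cut to their upper 50% they were 7.27 (5.78 to 8.77) and 13.8 (11.7 to 15.9). Nor is list order the whole cause of joint retention, whose odds ratio within 10% steps of both lists was 1.71 (1.55 to 1.9). The odds ratio was 1.70 among the first 50% of p300 rows, 1.72 at equal lengths and 1.27 (1.09 to 1.48) in the upper 50% of all lists. Row order is an imprecise measure of strength, so a second factor at a site may still mark stronger sites within a list part, and a lower enrichment of the pioglitazone libraries and an effect of pioglitazone both stay open and untested.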
